A study of Escherichia coli with 4 samples.

How the data were processed

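Escherichia coli MG1655, a K-12 reference strain, was grown in aerobic chemostats limited by glycerol. Total RNA from cells taken just before S-nitrosoglutathione (GSNO) was added and from cells taken 5 min after 200 µM GSNO was hybridised together on arrays with 2 channels. The labels name 2 chemostats with 2 runs each, which gave 4 arrays. GSNO RNA was in channel 2 in run 1 and in channel 1 in run 2 of each chemostat, per the labels. The arrays are called 1 and 2 (chemostat 1, runs 1 and 2) and 3 and 4 (chemostat 2, runs 1 and 2).

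The deposited values were 1 signed log ratio per spot and array, and the authors' use of log2 or another base is not stated. How the authors scanned, filtered and normalized the arrays is not given in the sources used here, and spot intensities were not analysed here. A base of 10 was set aside, because the most extreme ratios would then span nearly the whole range of a scanner. Bases 2 and e could not be told apart, so values are given as log ratios on the deposited scale and folds hold only if the base was 2. Array medians were 0.0012, -0.0484, -0.0015 and -0.0387 on arrays 1 to 4, and the SDs over all spots were 0.445, 0.439, 0.633 and 0.515. Each array was centred on its median. No spot lacked a value.

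Which way each ratio runs is not stated either. The rule set before the data were examined took the sign of the correlation between the 2 arrays of a chemostat over all spots, and it did not settle the matter. Pearson's r was -0.08 in chemostat 1 and 0.0003 in chemostat 2, against 0.23 and 0.25 between arrays of the same channel order in different chemostats. Spearman's rho was -0.131 in chemostat 1 and -0.0357 in chemostat 2. Between arrays of opposite channel order in different chemostats, rho was -0.0866 (arrays 1 and 4) and -0.201 (arrays 2 and 3). By rank, the rule thus leaned weakly towards turning run 2. The values were used as deposited, as if the authors had already turned run 2, with positive values taken as higher with GSNO. This reading is likely rather than settled, and it was chosen after gene values had been seen. Its basis is that norV and hcp, textbook nitric oxide-induced genes, and 11 of 15 methionine genes, which the study is known to report as raised, were positive on all 4 arrays. Turning run 2 must break any such set of signs, so these genes prompted the choice and do not test it. The nitric oxide list barely separated the readings, with 1 direction on all 4 arrays for 3 of 13 genes as deposited and 2 with run 2 turned. Neighbouring genes on the chromosome, which often share a transcript, had closer values as deposited (r = 0.187 over 3631 pairs) than with run 2 turned (r = 0.133). These pairs include norV, hcp and methionine genes, and r was not computed without them. It is therefore not support separate from the genes that prompted the choice. Against the reading as deposited, the 2 chemostat means correlated more strongly across genes with run 2 turned (r = 0.282 against 0.174). With run 2 turned, 463 genes had an unadjusted p under 0.05 in limma, against 270 as deposited.

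Of 4608 spots, 4087 had 1 gene in the platform annotation, 521 had none and 0 had several. Entrez identifiers matched 4086 spots to the RefSeq gene table of assembly ASM584v2, which updated 197 symbols. That table was used for names, gene order and gene length only, and no coordinates are given because the sources name no build. Spots of a gene were averaged, which left 4038 genes, 49 of them with more than 1 spot.

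The 2 arrays of a chemostat were taken as a channel swap of the same 2 RNA extracts and averaged, so that n = 2 chemostats. That the extracts were the same is read from the titles and is not stated. P-values of single genes therefore rest on the spread between these 2 cultures, each compared with its own sample from before GSNO. That spread is drawn strongly towards a prior from all genes. P-values of the list and permutation tests compare genes with other genes and do not measure the spread between cultures. The mean log ratio was tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3) and Benjamini-Hochberg adjustment at 0.05. The fit had 1 residual and 8.17 prior degrees of freedom. Genes with a log ratio of at least 1 in 1 direction on all 4 arrays were also counted, without a test.

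A total of 25 gene lists, fixed before the data were examined, were tested with limma's camera (2-sided, preset correlation of 0.01, adjusted over the 25 lists). Of 508 listed entries, 504 were measured. Camera was repeated with a correlation estimated for each list from the 4 arrays after removing the mean and a channel effect, negative estimates being set to 0. The methionine list and the genes fixed by name were chosen in knowledge of what the study reports, so they are not independent evidence of direction.

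Genes are named by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls past the threshold with 1 direction on all 4 arrays, filled up from genes with a mean change of at least 2-fold. It adds 13 fixed genes (hmp, norV, norW, ytfE, hcp, frmA and 7 met genes), the 4 largest members of each list past the threshold and at most 2 of each other list. It gave 76 genes, with 5 rises and all 8 falls filled in. Genes outside it are said to be so.

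In 20 simulations over 4038 genes, 200 of them changed, variances were drawn from limma's prior for all genes, with a channel effect that cancels. There the test called 86.6% of genes changed by a log ratio of 1, 99.9% at 2 and 100% at 3. In these simulations, 7.18% of calls were unchanged genes. Changed genes had the spread of all genes (prior SD 0.265), whereas metB and metR had SDs of 1.73 and 1.42 in the data. The shares are therefore too favourable for such genes. Camera found a list shifted by 1 in 10 of 10 simulations and called 0 other lists, but with genes drawn independently. The estimated correlation within a list reached 0.747 in the data.

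The alternatives set before the data were examined were the values without centring, equal spread on all arrays, medians over spots, each array or chemostat left out, the chemostat as a random block, 4 independent arrays, a channel effect, another variance prior, other thresholds, other list tests and a turned sign. Turning run 2, testing all spots, centring within the 16 print blocks splitting the variance prior and testing NtrC and CysB targets by gene cluster and with run 2 turned were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.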

Results

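The response of E. coli MG1655 to GSNO, a nitric oxide donor that also transfers nitroso groups to thiols, was measured in glycerol-limited aerobic chemostats. The medium held 54 mM glycerol, the dilution rate was 0.2 per hour, and dissolved oxygen was held at 40% of air saturation. RNA from before and 5 min after 200 µM GSNO was compared on 4 arrays, 2 from each of 2 chemostats, with the channels exchanged between the 2 arrays of a chemostat. The arrays gave a log ratio for 4038 named genes. Values are mean log ratios on the deposited scale ± SD over n = 2 chemostats, and positive values mean higher with GSNO, a direction that is likely but not settled. The SD leaves out the spread between the 2 arrays of a chemostat. The number of arrays limits the precision.

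Genes of methionine biosynthesis and uptake rose as a group. All 15 measured members had a positive mean, 11 were positive on all 4 arrays, and the list's mean log ratio was 1.21 ± 0.75 (camera, adjusted p = 1.01e-20). The call held with an estimated correlation of 0.747 between the list's genes (adjusted p = 0.0133). In the direction taken here, the list mean was 0.68 in chemostat 1 and 1.74 in chemostat 2, and all 15 members were higher in chemostat 2. This order rests on that direction, because with run 2 turned the 2 arrays of a chemostat would largely cancel. Over all genes, 2 members passed limma's test, metF, encoding methylenetetrahydrofolate reductase (2.65 ± 1.22, adjusted p = 0.0149), and metA, encoding homoserine O-succinyltransferase (1.96 ± 0.96, adjusted p = 0.038). If the base was 2, these are changes of 6.27-fold and 3.89-fold.

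Adjusted over the list alone, 12 of the 15 methionine genes passed and 3 did not. The 3 were metC, metH and metL, singled out after their values were seen, at 0.33, 0.01 and 0.34. Other members had large values that missed the threshold over all genes. Cystathionine gamma-synthase metB had a mean of 2.66 ± 1.73 (adjusted p = 0.0779), and metR, the activator of metE and metF, had 2.39 ± 1.42 (adjusted p = 0.0602). The methionine importer ATPase metN had 1.56 ± 1.03, the repressor metJ 1.49 ± 1.17 and S-adenosylmethionine synthetase metK 1.23 ± 0.89, with adjusted p of 0.117, 0.187 and 0.187. The cobalamin-independent methionine synthase metE had only 0.58 ± 0.39 (adjusted p = 0.516), and it was negative on array 1 (-0.35).

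Genes of nitric oxide detoxification rose as a group too, carried by a few members. The 13 genes had a mean of 0.68 ± 0.01 and a median of 0.17 (camera, adjusted p = 2.13e-06, and adjusted p = 5.98e-05 with an estimated correlation). Their mean was 1.00, 0.37, 0.41 and 0.93 on arrays 1 to 4, so the SD over chemostats hides a wide spread between arrays. Over all genes, 2 of the 13 passed. The flavorubredoxin nitric oxide reductase norV had 2.79 ± 1.09 (adjusted p = 0.0101), and the hybrid cluster protein gene hcp had 2.58 ± 1.18 (adjusted p = 0.0149). The lowest value on any array was 1.92 for norV and 1.29 for hcp, and both were higher in chemostat 1 (3.56 and 3.41) than in chemostat 2 (2.02 and 1.75).

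Adjusted over the list alone, 4 nitric oxide genes passed, which added hmp and ytfE. The flavohaemoglobin gene hmp had a mean of 1.12 ± 0.97 (adjusted p = 0.311 over all genes), with 3.15 on array 4 and values between 0.21 and 0.66 on the other 3 arrays. The iron-sulphur repair gene ytfE had 0.96 ± 0.89 (adjusted p = 0.37), with 2.54 on array 4 and -0.03 on array 2. The norV partner gene norW had 0.42 ± 0.08 (adjusted p = 0.698), with 1.03 on array 1 and -0.08 on array 2. The gene frmA, whose glutathione-dependent formaldehyde dehydrogenase also reduces GSNO, had -0.26 ± 0.22 (adjusted p = 0.998).

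**Figure D1:**
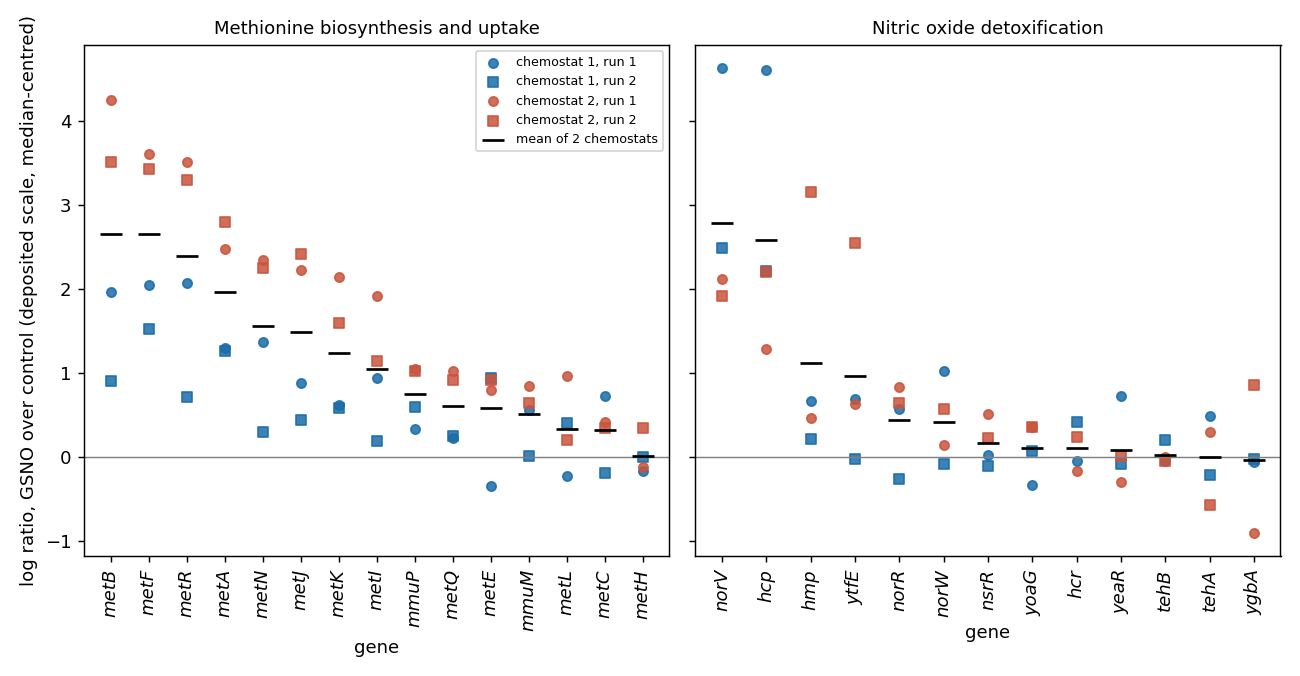
Log ratio (GSNO over control, deposited scale, median-centred) of each measured gene of the methionine list (left, 15 genes) and the nitric oxide list (right, 13 genes). Circles are run 1 and squares run 2 of chemostat 1 (blue) and chemostat 2 (red), and bars are means of the 2 chemostats. In the direction taken here, the methionine genes are higher in chemostat 2, whereas norV and hcp are highest on array 1 (4.63 and 4.61).

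Across all 4038 genes, 7 passed limma's test and all 7 were higher with GSNO in the direction taken here. Besides norV, hcp, metF and metA they were dgcJ, ybdL and cyuP. The array annotation lists dgcJ, a diguanylate cyclase gene, as yeaJ, and it had 1.96 ± 0.04 (adjusted p = 0.00528). Its single arrays ranged from 1.35 to 2.61. The gene ybdL, encoding an aminotransferase that prefers methionine, had 1.89 ± 0.35 (adjusted p = 0.00773), and cyuP, a cysteine transporter gene annotated as yhaO, had 2.31 ± 1.00 (adjusted p = 0.0149). A log ratio of at least 1 in 1 direction on all 4 arrays was found for 6 genes, dgcJ, ybdL, norV, metF, hcp and metA, all higher; with the run 2 arrays turned there were 3 such genes, all lower. Any size of change in 1 direction on all 4 arrays was found for 495 genes, 12.3% of those measured, where 4 independent signs give 12.5%.

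The single-gene calls depended on the spread model. The count was 0 with a channel effect, and 0 with a trended, robust variance prior. Under that prior 0 genes had even an unadjusted p under 0.05 in limma, against 270 in the test used here. Its trend was fitted on the mean log ratio itself. The most changed genes then get the widest prior, so this setting cannot judge their calls. The count was 0, 7, 12 and 2 when arrays 1, 2, 3 and 4 were left out in turn (4 of those 7 were the same genes). Leaving out 1 array also breaks the channel swap of its chemostat, so a channel effect no longer cancels there. With the run 2 arrays turned the count was 2, both of them lower and neither among the 7 genes called here.

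**Figure D2:**
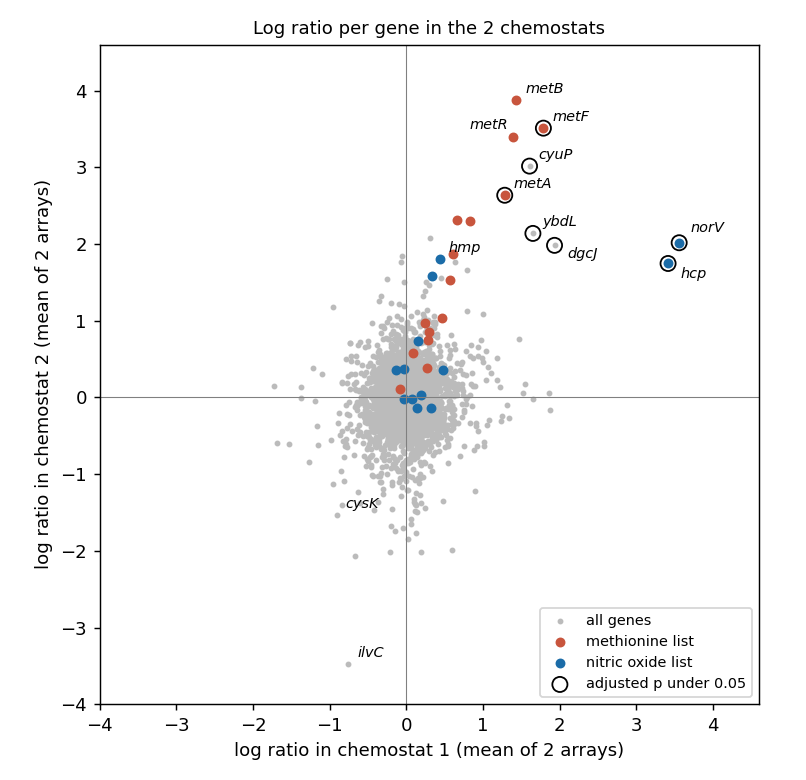
Log ratio (GSNO over control, deposited scale) of each of 4038 genes in chemostat 1 (horizontal) and chemostat 2 (vertical), each the mean of 2 arrays. Red points are the methionine list, blue points the nitric oxide list and rings the 7 genes past the threshold. In the direction taken here, all 15 methionine genes lie above the diagonal, and norV and hcp below it.

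No gene passed as lower in the direction taken here. In that direction, the largest negative means with 1 direction on all 4 arrays belonged to 8 genes, none of which passed. With the run 2 arrays turned the order differed, with tfaX at -1.82 and wcaD at -1.60 (adjusted p = 0.0373 for both), singled out after their values were seen, and ilvC at -0.77. The acetohydroxyacid isomeroreductase gene ilvC had the largest of the 8, -2.12 ± 1.92 (adjusted p = 0.202), with -0.76 in chemostat 1 and -3.48 in chemostat 2. Next came yhdW, which resembles an amino acid transporter gene (-1.37 ± 0.99), and cysK, encoding cysteine synthase A (-1.22 ± 0.44, adjusted p = 0.0779). The lipopolysaccharide export gene lptG had -1.14 ± 0.77, with -3.35 on array 2 and -0.01 on array 1. Cytosine permease codB had -1.12 ± 0.40 (adjusted p = 0.0947) and sgcR had -1.12 ± 1.28. The means of yeaD and of nac, a regulator of nitrogen assimilation, were -1.06 ± 0.30 and -1.04 ± 0.12 (adjusted p = 0.0947 and 0.0779).

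Among the 25 lists, 7 passed camera's test, 2 higher and 5 lower, and 4 of the 7 held with an estimated correlation. For the iron list that estimate was 0, below the preset 0.01, so its repeat was not a stricter test. With the run 2 arrays turned 0 lists passed, so every list call, methionine and nitric oxide included, rests on the direction taken here. Purine and pyrimidine biosynthesis was lower and held. Its 23 genes had a mean of -0.29 ± 0.09, and 20 of them were negative (adjusted p = 6.18e-07, and adjusted p = 0.00171 with an estimated correlation). The genes codB, pyrI, guaB and purK had the largest means, from -1.12 to -0.50, and 0 members passed over all genes or, except codB, over the list alone. With run 2 turned, the means of these genes were -0.03, -0.15, -0.54 and -0.31, so the order rests on the direction taken here.

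Ribosomal protein genes were lower by a small amount. Of 54 genes, 45 had a negative mean, and the list mean was -0.20 ± 0.07 (adjusted p = 1.01e-07). The call was lost with an estimated correlation (adjusted p = 0.134). In the direction taken here, the largest means belonged to rpsG (-0.77 ± 0.31) and rpsA (-0.71 ± 0.55), and 0 genes passed over all genes or over the list alone. With run 2 turned, rpsG and rpsA were at -0.05 and -0.04, and rpsJ at -0.33.

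The cysteine and sulphate list was also lower, with a mean of -0.20 ± 0.16 over 28 genes, 18 of them negative (adjusted p = 0.00206). The call was lost with an estimated correlation (adjusted p = 0.134) and without array 4 (adjusted p = 0.11). Adjusted over the list alone, 4 genes fell. They were cysK, cysP of sulphate uptake (-0.93 ± 0.43), cysI of sulphite reduction (-0.73 ± 0.40) and the regulator gene cbl (-0.66), the last singled out after its value was seen. The sulphite reductase gene cysJ had -0.87 ± 1.17, with -0.04 in chemostat 1 and -1.70 in chemostat 2.

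Arginine biosynthesis and iron acquisition also passed as lower. The 13 arginine genes had a mean of -0.30 ± 0.39, nearly all of it from chemostat 2 (-0.57, against -0.02 in chemostat 1; adjusted p = 0.00206). The arginine call was lost with an estimated correlation (adjusted p = 0.156) and without array 1 (adjusted p = 0.0973). In chemostat 2 argI and argA were at -2.02 and -1.99, and in chemostat 1 they were at 0.19 and 0.60. The split of the arginine genes by chemostat rests on the direction taken here. With run 2 turned, the means of argI and argA over the 2 chemostats were 0.15 and -0.40. The 36 iron genes had a mean of -0.12 ± 0.07 with 25 negative (camera, adjusted p = 0.0243). With an estimated correlation of 0, below the preset 0.01, camera's adjusted p was 0.0133. The largest falls were those of the enterobactin genes entE (-0.75 ± 0.63) and entB (-0.61 ± 0.78), whereas entA and entC were positive (0.03 and 0.15). With run 2 turned, entE and entB were at -0.01 and -0.22, and fepD at -0.71. The iron call was lost without array 1, 2 or 4 (adjusted p = 0.0973, 0.057 and 0.288) and with 1 value per run of neighbouring genes (adjusted p = 0.461).

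**Figure D3:**
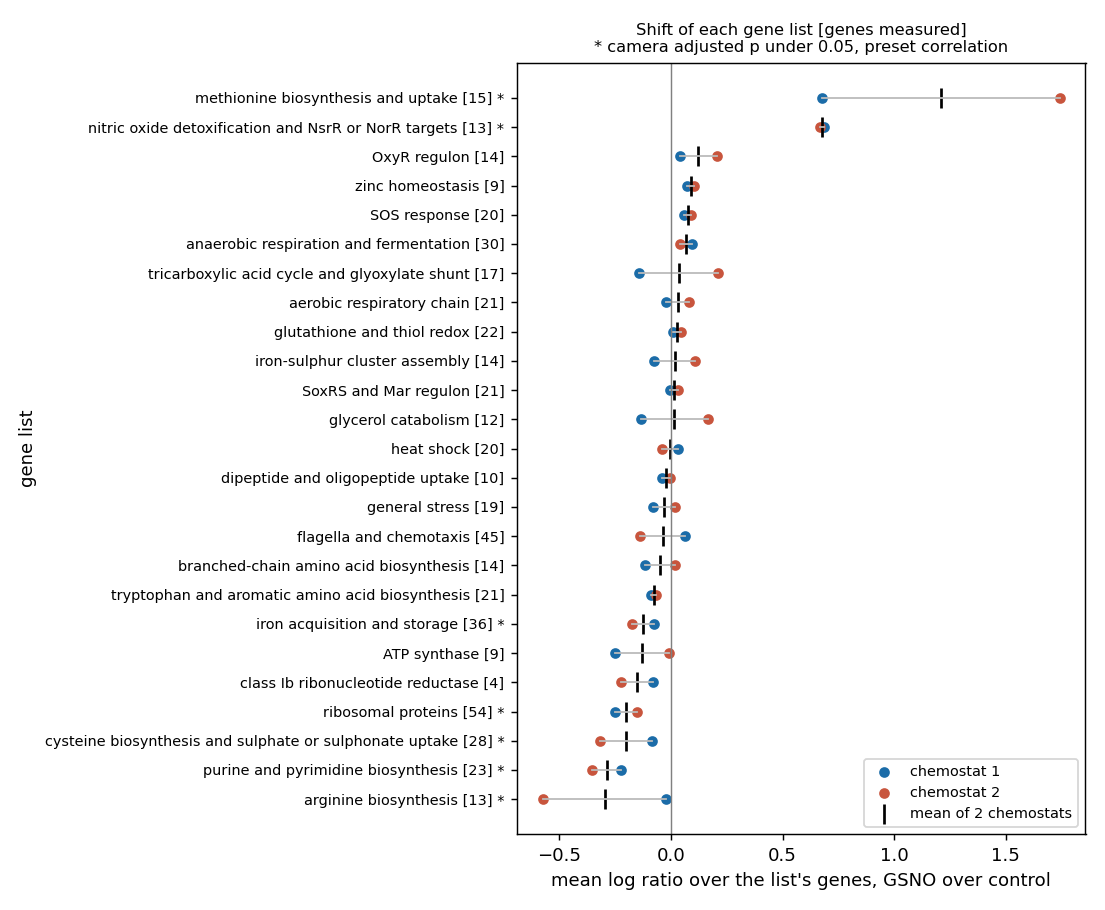
Mean log ratio (GSNO over control, deposited scale) of the measured genes of each of 25 lists in chemostat 1 (blue), chemostat 2 (red) and their mean (black bar), with the number of genes measured in brackets. Asterisks mark the 7 lists past camera's threshold with a preset correlation; methionine (1.21) and nitric oxide (0.68) lie apart from the rest, which run from -0.30 to 0.12.

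The other 18 lists did not pass. Among oxidative and nitrosative stress lists, the mean was 0.12 for OxyR targets (adjusted p = 0.221), 0.01 for SoxRS and Mar, 0.02 for iron-sulphur cluster assembly and 0.03 for glutathione and thiol redox. In them soxS had 0.81 ± 0.81 and the cluster assembly repressor gene iscR 0.90 ± 1.34, the latter at -0.05 in chemostat 1 and 1.84 in chemostat 2. Other stress lists had means of 0.07 (SOS response), -0.003 (heat shock), -0.03 (general stress) and 0.09 (zinc homeostasis). Energy metabolism gave 0.07 for anaerobic respiration and fermentation, 0.03 for the tricarboxylic acid cycle, 0.03 for the aerobic respiratory chain, -0.13 for ATP synthase and 0.01 for glycerol catabolism. The respiratory oxidase genes cydA and cydB were positive on all 4 arrays (0.42 ± 0.35 and 0.53 ± 0.25), and narX, a nitrate sensor gene, had 0.96 ± 0.24 and passed over its list alone (adjusted p = 0.117 over all genes). The remaining means were -0.15 (class Ib ribonucleotide reductase), -0.02 (peptide uptake), -0.04 (flagella and chemotaxis), -0.05 (branched-chain amino acids) and -0.08 (tryptophan and aromatic amino acids). In the last list tnaA, encoding tryptophanase, had 1.04 ± 0.06 and passed over the list alone (adjusted p = 0.0779 over all genes), as ilvC did in the branched-chain list. On single arrays tnaA ranged from 0.56 to 1.45. Median, mean and test differed in sign for the SoxRS, cluster assembly, branched-chain, tricarboxylic acid and respiratory chain lists.

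The 2 chemostats resembled each other little beyond the largest changes. Across genes, which are not independent replicates, their mean log ratios correlated with Pearson's r = 0.174 and Spearman's rho = 0.0159. With the run 2 arrays turned, r was 0.282 and rho 0.298.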

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

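The test of array spread and the comparison of single arrays on the methionine list were chosen after the results were seen. So were the comparison with the nitric oxide list and the look at array 3 for hmp. Among 101 genes and lists, 10 had 1 array far from the other 3, where chance gives about 1 in 20; 4 of the 10 stood out on array 2, 4 on array 3, and 1 each on arrays 1 and 4.

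In the direction taken here, the methionine genes were higher in chemostat 2 than in chemostat 1, with list means of 1.74 and 0.68, a ratio of 2.58. The list means were 0.82 and 0.53 on arrays 1 and 2, and 1.83 and 1.65 on arrays 3 and 4. With run 2 turned, each pair would largely cancel and the order would not hold. A wider spread of the chemostat 2 arrays is argued against as the whole cause, because the ratio was still 1.81 after the arrays were scaled to the same spread. A channel effect of equal size in both runs cancels in each chemostat mean by design, so it could not produce the order. The lower chemostat 2 array lay 0.833 above the higher chemostat 1 array in list mean, so the order did not rest on 1 array. The nitric oxide list did not decide whether chemostat 2 responded more in general, with a difference of -0.0161 (SE 0.249 over 13 genes), and norV and hcp were higher in chemostat 1. A difference in state between the 2 cultures or in the time of sampling may remain, and was not tested.

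The flavohaemoglobin gene hmp was at 3.1492 on array 4, with the other 3 arrays between 0.2146 and 0.6617. A local blemish is argued against, because the 8 spots around it on that array had a median of -0.116 and 0 were above 1. The other array of chemostat 2 had 0.462, within the range of chemostat 1, whereas a culture that differed would be expected to raise both arrays. That value was part of the flag itself, so it is not a separate test. A fault of that single spot, or extracts that differed between the 2 runs, could remain and was not tested; ytfE, another nitric oxide gene, was also highest on array 4 (2.54).

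Some log ratios followed the channel and not the treatment. The part of each gene's log ratio that changed sign with the channel correlated between chemostats with r = 0.282 across genes, against 0.174 for the mean log ratio, and tfaX and wcaD, singled out after their values were seen, changed sign between runs in both chemostats. Gene length had no such relation (rho = -0.0257) and does not account for the pattern. Centring within print blocks left the correlation at 0.255, so differences between blocks account for little of it. Position inside a block was not tested. A labelling bias of single genes may be the source, and so may deposited values that follow the channels, in which case this part would be the response; the former was not tested, and the latter is the reading set aside when the direction was chosen.

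Other genes with 1 array far from the rest were as follows. On array 3, sgcR was at -3.5269 (others -0.5164 to -0.0722), sufE at -2.1418 (others -0.2093 to -0.1516), lexA at -0.1231 (others 0.7537 to 0.8643) and trpE at -1.0538 (others -0.5064 to -0.4699). On array 2, yeaD was at -1.6923 (others -0.9217 to -0.7705), frmA at 0.2569 (others -0.4791 to -0.3536), carA at -0.115 (others -0.8038 to -0.762) and glpX at 0.7577 (others -1.0168 to -0.908). On array 1, metE was at -0.3456, with 0.8013 to 0.9465 on the others.

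A signal also appeared among the spots without a gene name, which the comparisons left out. The spot in position 4.2.15.14 had a mean log ratio of 2.2482, with 3.15, 1.98, 1.30 and 2.56 on arrays 1 to 4, and passed limma's test when all 4608 spots were tested (adjusted p = 0.0327).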

How the results depend on the processing

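The methionine, nitric oxide and purine and pyrimidine lists kept their direction and their call in all 15 tested settings other than run 2 turned, with list means of 1.14 to 1.28, 0.52 to 0.83 and -0.40 to -0.17. Ribosomal proteins kept theirs in 14 of 15, arginine in 13, cysteine in 11 (also lost with a trended, robust prior, adjusted p = 0.0683, and against random lists, 0.0922) and iron in 10 (also lost within print blocks, 0.0537). Settings that changed only the test reused the same list means, so there the direction could not change. Single-gene calls were far less stable. Against 7 genes in the test used here, 3 passed with arrays scaled to the same spread, 2 with the chemostat as a random block (correlation -0.267), 1 with 4 independent arrays, 0 with a channel effect (250 at an unadjusted p under 0.05 in limma), 0 with a trended, robust prior (0 unadjusted), 14 at adjusted p under 0.1 and 270 at unadjusted p under 0.05. Leaving out 1 array gave 0 to 12 genes (176 unadjusted without array 1); without array 2 or array 3 metB (adjusted p = 0.0408 and 0.0136) and metR (0.0203 and 0.0136) passed. Settings added after the data were seen gave 2 genes with run 2 turned (both lower), 3 when all spots were tested, 1 within print blocks, 0 with a trend alone (83 unadjusted) and 2 with a robust prior alone. With a trend alone, fitted on the mean log ratio itself, the prior variance was 3.68 to 50.2 at the 7 called genes. It was 0.0701 for all genes without a trend. The loss of these genes under a trend was thus nearly fixed in advance, and the causes of the other losses were not tested. At the threshold used here, the 7 called genes kept their sign in all 15 settings with a test other than run 2 turned (there metA was at -0.07). That was nearly fixed in advance, because all 7 were positive on all 4 arrays and several settings reused the same mean. In these 15 settings, dgcJ and ybdL were past the threshold in 9, cyuP and metF in 5, norV in 4, hcp in 3 and metA in 2. Against 6 genes with a log ratio of at least 1 on all 4 arrays, there were 6 to 14 without 1 array, 36 without chemostat 1, 11 without chemostat 2, 15 at 1.5-fold, 1 at 3-fold and 3 with run 2 turned, all lower. Against 7 lists, 4 passed with an estimated correlation, and 0 with run 2 turned (2 at an unadjusted p under 0.05 in camera, and 463 genes in limma). Turning the sign on all 4 arrays keeps the counts of 7 genes, 6 genes and 7 lists and reverses every direction by construction. Lists near 0 that did not pass also changed sign: without centring, SoxRS (-0.0069), cluster assembly (-0.0054) and glycerol catabolism (-0.0069); with scaled arrays, heat shock (0.0027), the tricarboxylic acid cycle (-0.0018) and glycerol catabolism (-0.0069); within print blocks, glycerol catabolism (-0.0144). Leaving out 1 array or 1 chemostat gave ranges of -0.0725 to 0.1024 for SoxRS, -0.0749 to 0.1077 for cluster assembly, -0.1352 to 0.165 for glycerol catabolism, -0.0382 to 0.0314 for heat shock, -0.1444 to 0.2119 for the tricarboxylic acid cycle, -0.1735 to 0.0765 for branched-chain amino acids, -0.1094 to 0.0496 for general stress, -0.1381 to 0.0647 for flagella and -0.0201 to 0.0818 for the respiratory chain. Over the same arrays and chemostats left out, oppC ranged from -0.3504 to 0.0868 and hslU from -0.5156 to 0.1335. Of the 76 named genes, only these changed sign with 1 array left out (oppC at 0.0116 without array 1, hslU at 0.1335 without array 2). Without chemostat 2, 9 did, which were oppC, argI, argA, fepD, ilvM, trxC, glpF, iscR and sdhD (0.09, 0.19, 0.60, 0.10, -0.07, -0.13, -0.22, -0.05 and -0.20), and without chemostat 1 none did. A rule for missing values changed nothing, since no value was missing; camera takes no block, so no list was tested under it; and 1 chemostat alone leaves no test. Signal over background was not analysed here, so how it limits dim genes is unknown.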

Other observations

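The hypotheses on nitrogen and cysteine genes below came from the largest falls of the same data. Their first tests were set down before the results were seen, and the tests by gene position and by cluster after. Nitrogen assimilation genes, apart from codB of the purine and pyrimidine list, were on none of the 25 lists. Among the largest negative means, nac, codB and yhdW are activated under nitrogen limitation by NtrC, directly or through Nac, and 5 more such genes had been seen at low values (glnK, glnA, glnQ, rutR and hisP). Together these 8 had a median log ratio of -0.99. The hypothesis that NtrC-activated genes fell as a group was tested on 41 further targets. Their median was -0.282, 34 of the 41 were negative and 19 were negative on all 4 arrays (camera, p = 3.48e-12 with a preset correlation and p = 1.66e-05 with an estimated one). That set held operon partners and close neighbours of the 8, among them amtB, glnG, glnL, hisJ and the rut genes, so it was not independent of them. The 22 targets more than 10 gene positions from all 8 had a median of -0.205, with 17 negative and 9 negative on all 4 arrays (camera, p = 3.19e-05 with a preset and p = 0.00362 with an estimated correlation). They formed 6 clusters of neighbouring genes, 5 of them with a negative mean (permutation test that rotated the set through all 4037 positions on the chromosome, 1 value per cluster, p = 0.00694). Members of the first set with the lowest values were glnG (-0.94), ddpX (-0.69), ddpF (-0.65), glnL (-0.61) and rutA (-0.59), whereas the 5 genes astA to astE lay between 0.01 and 0.15. The fall rests on the direction taken here, since with run 2 turned neither set passed. The medians were then -0.0154 for the 41 targets and -0.0606 for the 22 targets (camera with a preset correlation, p = 0.724 and p = 0.769). In that direction the data are consistent with a modest fall of NtrC-dependent transcription within 5 min of GSNO, as a hypothesis; 0 of these genes passed alone, and glutathione or its glycine and glutamate as a nitrogen source was not tested.

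The cysteine transporter gene cyuP rose while cysK, cysP and cysI were low, and the thiosulphate uptake genes tsuA (-0.95) and tsuB (-0.99), singled out after their values were seen, were low on all 4 arrays. The fall was not shared by the whole cysteine list, where 10 of 28 genes had a positive mean. There cysU, cysW, cysA and cysM were at -0.08, -0.03, 0.24 and 0.02. GSNO carries a cysteine residue, and a cysteine surplus lowers transcription by CysB. If the cells responded to such a surplus, further CysB targets outside the cysteine list would also be low. The 9 tested had a median of -0.21, 7 were negative and camera gave p = 0.0219 with a preset and p = 0.0172 with an estimated correlation of 0. But gsiA to gsiD and iaaA share 1 operon, and tcyL and tcyN lie in that of tcyJ, a member of the cysteine list. Without those 2 and with 1 value per cluster, 3 clusters were left with a median of -0.181 (the same permutation test, p = 0.0907, and p = 0.105 with all 4 clusters). With run 2 turned, the 9 targets had a median of 0.108 with 3 negative. Whether cells responded to a cysteine surplus is therefore not settled. The cystine uptake gene tcyP had -0.42 and the glutathione importer genes gsiC and gsiD -0.39 and -0.32, whereas gsiA had 0.22. A test on cyuA, the neighbour of cyuP that degrades cysteine, had been chosen first; that gene had no named spot and was not analysed here, so the test on further CysB targets took its place before their values were seen.

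The neighbours of called genes on the chromosome were looked up after the calls, and both neighbours of cyuP had no named spot. Beside metA, yjaB and aceB had -0.01 and -0.06. Beside hcp, its reductase gene hcr had 0.11 and lysO -0.20, and beside norV, norW and norR had 0.42 and 0.45. Beside ybdL, hcxA had 0.88 (limma, adjusted p = 0.429), with 1.98 on array 4 and 0.03 on array 2, and ybdM had 0.11. Beside dgcJ, cdgI and yeaK had 0.35 and -0.09, and beside metF, metL and katG had 0.34 and 0.18.

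A total of 5 spots without a gene name, picked for the largest change of sign between runs, had values as low as -4.21 on array 3 and as high as 3.37 on array 2. Their positions were 4.3.15.15, 4.3.15.16, 4.3.15.18, 2.1.15.18 and 2.1.16.1, some of them side by side. Turning the signs of the arrays in the 8 possible patterns gave 7 called genes for the deposited signs and at most 2 for another pattern, with 6 and 3 genes at a log ratio of at least 1 on all 4 arrays. The 8 patterns are too few for a share under 0.05.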
